A study of Mus musculus with 4 samples.

How the data were processed

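Gene expression was measured in primary astrocyte cultures prepared from 4 brain regions of CD-1 mouse pups at postnatal day 3, with 1 Affymetrix mouse array per region and all 4 samples numbered as the first biological replicate. Per the labels' protocols, dissected tissue was dissociated and plated in medium with 10% serum, adherent cells were shaken at 200 rpm to enrich astroglia, replated and grown to monolayers, and biotinylated RNA was made from 2 ug of total RNA. The series' design text says that tissue came from 4 littermate pups and, in the next sentence, that tissue of 3 pups was pooled; which number holds is not settled here.

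The deposited table holds a signal intensity on a linear scale for 22690 probe sets per array. Per the submitters' processing notes it was made with GCOS 1.4; the algorithm and its settings are not given in the sources used here. The deposited intensities had 2% trimmed means of 400.1 to 400.2 on the 4 arrays, within the tolerance of 5% set for this, so they were used as they stood with no further scaling. The table gives no detection calls, so no probe set could be called present or absent, and a floor took their place. Global scaling of this kind assumes that the bulk of transcripts is equal between cultures, and a culture holding other cell types shifts all other genes relative to its own total.

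The floor was the median signal over all probe sets and arrays, 122.1, and lower values were raised to it before taking log2. The number of arrays limits the precision. Because the floor is the overall median, the share of probe sets above it, 49.1% to 52.2% on each array, is largely set by its definition. Signals near the floor are close to background, so a fold against a value at the floor is a lower bound and is given as "at least". The 3 prime to 5 prime signal ratio of the Gapdh control probe sets was 0.86 to 0.92 and that of beta-actin 1.27 to 1.49, from the deposited intensities.

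Gene names came from the platform's probe annotation: 20380 probe sets had 1 gene symbol, 691 had several and 1555 had none listed, beside 64 control probe sets. Of the 20380, 20351 were matched by gene identifier in a RefSeq gene table. Only probe sets with 1 symbol were used, and each of the 12393 genes was represented by its probe set with the highest mean log2 signal; 4956 genes had several. No coordinates are given, since the arrays name no genome build.

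A gene was called higher in a region when its log2 signal was at least 1 (2-fold) above the highest of the other 3 regions, and lower when at least 1 below the lowest. Pairs of regions were compared by the number of genes 2-fold or more apart in each direction and by correlation across the genes above the floor on at least 1 array. With 1 array per region there is no test between regions. Of 33 gene and marker lists, the median over members above the floor of log2 signal minus the mean of the other 3 regions was set against 10000 random lists of the same size, matched on mean signal in 10 bins. A list was said to stand apart below the 2.5 or above the 97.5 percentile, which describes these arrays and does not test the regions. Of 128 list medians 72 stood apart, where the limits alone let 6.4 do so. The 4 medians of a list are not independent, and on simulated data 8.0% of unshifted lists stood apart. Genes of a list can also vary together, which the random lists and the simulated data leave out. Setting 72 against 6.4 can therefore overstate the excess. The 72 were 13 in the subventricular zone, 21 in the ventral mesencephalon, 17 in the olfactory bulb and 21 in the hippocampus.

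The rules, the lists and the alternatives were fixed before the data were examined, other than those named in the closing section. Genes named in the text are the 10 higher and the 8 lower with the widest gap in each region, the 3 with the largest difference in each direction of a pair, and up to 4 members with the widest gap of each list that stood apart or held 3 or more called genes (those with the largest shift where none was called). Clone-type names were counted but not named. The levels of 7 astrocyte genes are always given. Further list members were named after their values were seen, mostly to complete a count. Members of a list that the annotation does not name are not analysed here.

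The scatter between probe sets was taken from genes whose 2 probe sets of highest mean signal were above the floor on all 4 arrays. It was a median-based SD, because the differences have long tails. For the difference in contrast between the 2 probe sets it was 0.26, against a plain SD of 0.34. For called genes with a second probe set above the floor on at least 1 array, the side of that probe set was compared. It was the same in 69 of 69 in the subventricular zone, 59 of 59 in the ventral mesencephalon, 111 of 112 in the olfactory bulb and 74 of 74 in the hippocampus. Any shift counted, however small, as for Slco2a1 (0.08) in the subventricular zone and Bdh1 (-0.06) in the ventral mesencephalon. The agreement therefore concerns the direction and not the 2-fold calls. The calling rule was tested on simulated data of 12393 genes with noise at the level between probe sets. It called 0 genes with no change, and 24.0%, 100.0% and 100.0% of genes raised 2-fold, 4-fold and 8-fold. The simulated noise was normal, without long tails or a spread between cultures, and the raised genes were drawn from those well above the floor. The 0 therefore follows from the small noise and gives no rate of false calls between cultures. Of random unshifted lists 8.0% stood apart in the subventricular zone.

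Alternatives were the floor at the 30th or 70th percentile, an offset in place of the floor, and quantile normalization or median scaling of the arrays. Genes were also taken as the mean of all their probe sets, or from probe sets with a plain identifier only. A plain identifier has only digits before the ending _at, so probe sets ending in _a_at, _s_at or _x_at were left out. Further alternatives were a threshold of 1.5-fold or 3-fold, and for lists the mean, all members and no shared members. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.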

Results

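Astrocyte cultures grown from 4 brain regions of CD-1 mouse pups, an outbred stock dissected at postnatal day 3, were compared. The regions were the subventricular zone, a germinal layer along the lateral ventricle, the ventral mesencephalon, which is the floor of the midbrain, the olfactory bulb and the hippocampus. Each culture was measured on 1 array of 22690 probe sets, of which those with a single gene name stood for 12393 genes. With 1 array per region, no difference given here has a replicate check, and no p-value was computed; the number of arrays limits the precision of every comparison. A signal floor of 122.1 was used, and 7987 genes lay above it on at least 1 array. The 2% trimmed means of the 4 arrays lay between 400.1 and 400.2. Scaling to a common value would produce this, so it does not show that the arrays are comparable. The signals of all 18 hybridisation control probe sets fell from the subventricular zone to the hippocampus array, by a median of 1.69-fold. The hippocampus array had 11835 probe sets above the floor and the others between 11144 and 11207, while its 99th percentile of signal was the lowest, 5619 against 6863 to 7377. Probe sets of the same gene gave a noise of 0.16 (median-based SD, log2 per array, from 1972 genes). These genes had both probe sets above the floor on all arrays, so genes near the floor are left out. The value covers the measurement of an RNA and not the spread between cultures. Genes are named by a rule set before the data were examined; others, named to complete a count or a pair of related genes, were chosen after their values were seen.

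The cultures differed widely in astrocyte genes. Gfap, the astrocyte intermediate filament, had a signal of 10027 in the hippocampus, 3800 in the olfactory bulb, 3112 in the subventricular zone and 1007 in the ventral mesencephalon. Aldh1l1, a folate enzyme used as an astrocyte marker, ran from 5106 in the subventricular zone to 311 in the olfactory bulb, with 1711 in the ventral mesencephalon and 1727 in the hippocampus; this rests on 1 of its 2 probe sets, the other being below the floor on all 4 arrays. The glutamate transporter Slc1a3 read 4328 in the hippocampus, 2533 in the subventricular zone, 706 in the olfactory bulb and 641 in the ventral mesencephalon. The water channel Aqp4 read 4916, 1956, 1575 and 3943 in the subventricular zone, ventral mesencephalon, olfactory bulb and hippocampus, and the glutamine synthetase gene Glul 3357, 1736, 3948 and 2891. S100b, a calcium-binding protein, was above the floor in the olfactory bulb (277) and hippocampus (269) only, and Slc1a2, the other main glial glutamate transporter, lay below it on all 4 arrays. Over the 33 astrocyte genes above the floor, the median log2 distance of a region from the mean of the other 3 was 0.67 in the hippocampus, -0.36 in the olfactory bulb and -0.78 in the ventral mesencephalon. These medians lay at percentiles 100, 0.0 and 0.0 of random lists matched on expression. In the subventricular zone it was 0.26 (percentile 99.64), with Aldh1l1 3.0-fold higher by that probe set, the lipase Pla2g7 at least 5.3-fold lower and Gja1 lower, and turned to -0.01 without the ventral mesencephalon array; the olfactory bulb value lost its place apart without the subventricular zone (-0.08) or the hippocampus array (-0.02). The hippocampus median was 1.08 without the subventricular zone array and the subventricular zone median 0.45 without the hippocampus array. Of the 10 alternatives chosen before the data were examined, 2 ended the place apart of the subventricular zone (floor at the 70th percentile, 0.13, and mean over members, 0.16) and 1 that of the olfactory bulb (all members, 0.00).

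**Figure D1:**
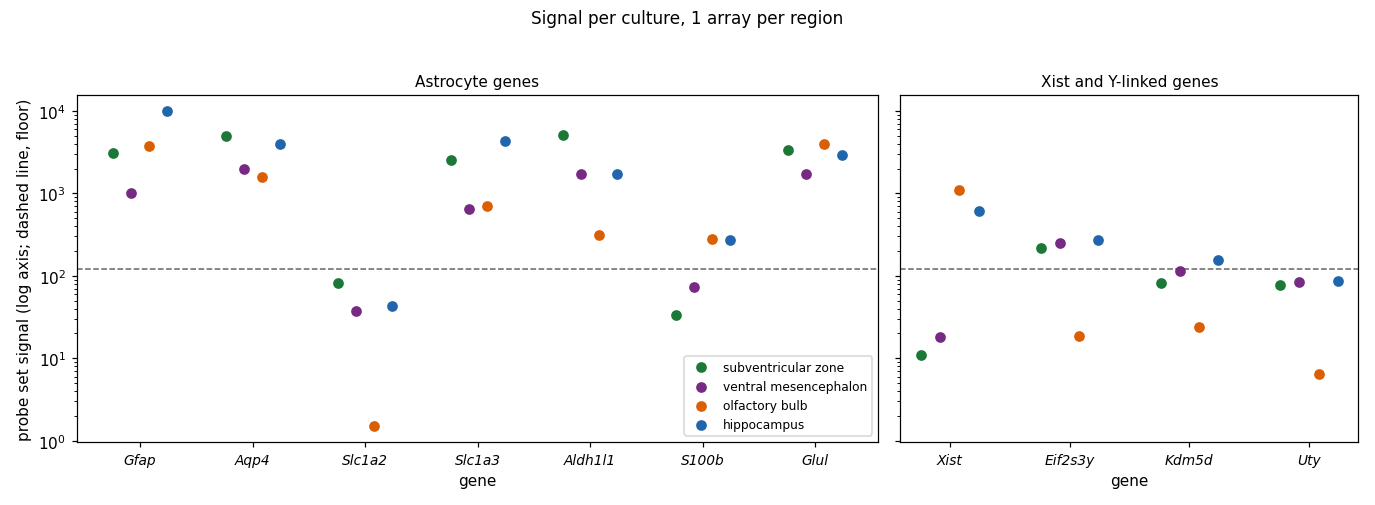
Probe set signal on a log axis for 7 astrocyte genes (left) and for Xist and 3 Y-linked genes (right), with 1 point per culture coloured by region and a dashed line at the floor of 122.1. Gfap runs from 1007 in the ventral mesencephalon to 10027 in the hippocampus, and Xist is above the floor only in the olfactory bulb (1110) and hippocampus (606).

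Markers of other cell types also differed between the cultures. The 29 microglia and macrophage markers above the floor had medians of 2.58 in the hippocampus and 1.52 in the olfactory bulb, against -2.04 in the subventricular zone and -1.91 in the ventral mesencephalon (percentiles 100, 100, 0.0 and 0.0). Lysozyme, Lyz2, read 11249 in the olfactory bulb and 9016 in the hippocampus but 179 and 82.3 in the subventricular zone and ventral mesencephalon, and Csf1r, the receptor that microglia need to survive, read 4073, 5099, 55.6 and 90.9 in the same order. The 26 fibroblast and meningeal markers had medians of 1.43 in the olfactory bulb, 0.86 in the ventral mesencephalon, -0.62 in the hippocampus and -1.61 in the subventricular zone (percentiles 100, 100, 0.0 and 0.0); the hippocampal median was -0.13 and no longer apart without the olfactory bulb array. The microglial list shared 4 and the fibroblast list 7 of these genes with other lists, and neither shared any with the astrocyte list. Neither the 6 endothelial markers (medians -0.16 to 0.16) nor the 10 pericyte and smooth muscle markers (-0.14 to 0.25) stood apart in any region. Over all alternatives the microglial medians ran from 1.61 to 3.67 in the hippocampus, 0.81 to 2.72 in the olfactory bulb, -3.06 to -1.18 in the subventricular zone and -3.34 to -1.30 in the ventral mesencephalon, and the direct median difference of the olfactory bulb minus the hippocampus was -0.32. Without the hippocampus array the bulb's microglial median was 2.60. The fibroblast medians were 0.90 in the olfactory bulb, 0.32 in the ventral mesencephalon and -1.52 in the hippocampus without the subventricular zone array, 1.72 in the ventral mesencephalon without the olfactory bulb array and -0.36 in the hippocampus without the ventral mesencephalon array.

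Transcripts of the sex chromosomes were not evenly spread over the cultures. Xist, the RNA of the inactive X chromosome, read 1110 in the olfactory bulb and 606 in the hippocampus, against 11 in the subventricular zone and 18.3 in the ventral mesencephalon. The Y-linked gene Eif2s3y read 219, 252 and 271 in the subventricular zone, ventral mesencephalon and hippocampus but 18.7 in the olfactory bulb. Kdm5d was above the floor only in the hippocampus (154), Uty on no array, and Ddx3y is not named here. As a list, the 3 sex-linked genes above the floor stood apart in no region (medians -0.11 to 0.52). The list joins Xist with Y-linked genes, which are opposed between the sexes. Its median therefore cannot show a difference in sex and says nothing against one.

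In the subventricular zone culture progenitor genes were high and matrix and fibroblast genes low. In the hippocampus matrix genes were low too, and progenitor genes were high (0.46) but turned to -0.29 without the olfactory bulb array. The telencephalic (10 genes, median -0.22, percentile 6.76) and ventral telencephalic transcription factors (9 genes, -0.12, percentile 21.48) of the subventricular zone did not stand apart as lists. In all, 102 genes were at least 2-fold higher there than in each other region and 81 were at least 2-fold lower. Crym, a thyroid hormone-binding protein, was 16.0-fold higher (signal 4089) and Spon1, the secreted adhesion protein F-spondin, 11.9-fold (2342). The other probe set of Spon1 was not above the floor on any array. The forebrain homeobox gene Six3 was at least 7.0-fold higher (857, with the other 3 at the floor). On the low side, apolipoprotein D (Apod, 43.0) was at least 35.0-fold lower, the fibrillar collagen gene Col3a1 (176) 29.9-fold and decorin (Dcn, 63.9) at least 19.0-fold. Further genes on the high side were the transcription factor Sox7 (at least 5.5-fold), the G-protein regulator Rgs8 (5.1-fold), the growth factor binding protein Igfbp3 (5.0-fold, signal 6151), the growth factor Pdgfb (4.9-fold), the elongation factor Eef1a2 (4.8-fold), the metalloreductase Steap4 (4.7-fold, 4724) and the prostaglandin transporter Slco2a1 (4.7-fold). Further genes on the low side were Igfbp4 (13.8-fold), the transcription factor Zic1 (at least 12.3-fold), the interferon-induced membrane protein Ifitm1 (12-fold), the ribonuclease Rnase4 (11.9-fold) and the matrix protein Tgfbi (at least 10.6-fold).

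Of the 29 neural stem and progenitor genes above the floor, 22 lay above the mean of the other regions in the subventricular zone (median 0.76, percentile 100). The adhesion molecule Vcam1 (7483) and the radial glial fatty acid-binding protein Fabp7 (14077) were each 2.3-fold higher, and no member was lower. Among 12 neuronal markers, 4 were higher (median 0.43, percentile 99.95): the GABA-synthesising enzyme Gad1 was 3.4-fold higher (671), Stmn2 2.6-fold (3465), Gap43 2.3-fold (400.0) and Uchl1 2.2-fold (1491). Its median was 0.17 (percentile 97.21) without the olfactory bulb array, 0.15 with the floor at the 70th percentile and 0.00 over all members, no longer apart in any. Of the 37 axon guidance and adhesion genes 4 were higher and 1 lower, with a median of -0.10 that did not stand apart (percentile 22.96). The 4 were the adhesion molecule Nrcam (4.4-fold), the guidance cue Ntn1 (2.3-fold, signal 4730), Sema3f (at least 2.2-fold) and N-cadherin, Cdh2 (2.1-fold). The semaphorin receptor Nrp2 was at least 2.6-fold lower. Without the olfactory bulb array the progenitor median was 0.49, and without the ventral mesencephalon array the neuronal one was 0.70.

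Fibroblast markers and matrix genes were low together in the subventricular zone. Of the 26 fibroblast and meningeal markers 8 were lower and 1, Islr, was higher (2.2-fold). Besides Col3a1 and Dcn, the retinoic acid-synthesising enzyme Aldh1a2 was at least 5.1-fold lower and the collagen Col6a2 4.9-fold. Of 50 extracellular matrix genes 8 were lower and none higher (median -0.51, percentile 0.0): Fbln1 was 8.6-fold lower, the gelatinase Mmp2 8.4-fold, the laminin chain Lamb1 at least 6.1-fold and Nid1 2.5-fold. The growth factors Igf2 (24.6, at least 7.6-fold lower), Igf1 (120, at least 4.3-fold) and Ptn (2.9-fold) were also lower, while the 28 neurotrophic and growth factors as a list did not stand apart (median 0.00, percentile 61.39). Interferon response genes had a median of 0.69 (31 genes, percentile 100), with 1 member, the antigen-presentation chain Cd74, higher (at least 3.9-fold). Without the ventral mesencephalon array the matrix median was -0.30 and the interferon median 1.28; the latter was 0.44 without the olfactory bulb and 0.42 without the hippocampus array.

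Smaller shifts were seen in other lists of the subventricular zone. The glutamate, GABA and ion handling list had a median of 0.37 (20 genes, percentile 99.99), with Kcnk1 (788), Gjb2 (88.3), the potassium channel Kcnj10 (2667) and Gja1 (2505) furthest from the other regions; Gja1 was 2.2-fold lower. The median was 0.10 and no longer apart without the ventral mesencephalon array, and lost its place under 3 of the 10 alternatives chosen before, with medians down to 0.00. The 13 Notch genes had a median of 0.36 (percentile 99.45), and 0.21, no longer apart, without the hippocampus array. It also lost its place apart under 7 of the 10 alternatives chosen before the data were examined, with medians down to 0.00; none was 2-fold away from all other regions, and Rbpj (320.3), Jag1 (86.9), Hes1 (659.7) and Hey1 (868) were shifted most. The olfactory ensheathing and Schwann cell list (-0.33, 18 genes) and the choroid plexus list (-1.02, 8 genes) stood apart on the low side, at percentiles 0.73 and 0.0; Fabp7 was higher in the first, and Aqp1 (31.0), Ttr (11.2), Slco1c1 (85.4) and Calml4 (52.6) were shifted most in the second. Without the olfactory bulb and the hippocampus array respectively these medians were 0.00 and -0.03 and no longer apart. The counts of the subventricular zone depended on which regions it was compared with: without the ventral mesencephalon array 274 genes were higher and 249 lower, and without the hippocampus array 304 and 200.0. With a gene taken as the mean of all its probe sets, Six3 and Slco2a1 were less than 2-fold higher (log2 gaps 0.94 and 0.77), and Sox7 with the floor at the 70th percentile (0.89). The ensheathing median was -0.63 without the ventral mesencephalon array and lost its place under 4 of the 10 alternatives.

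**Figure D2:**
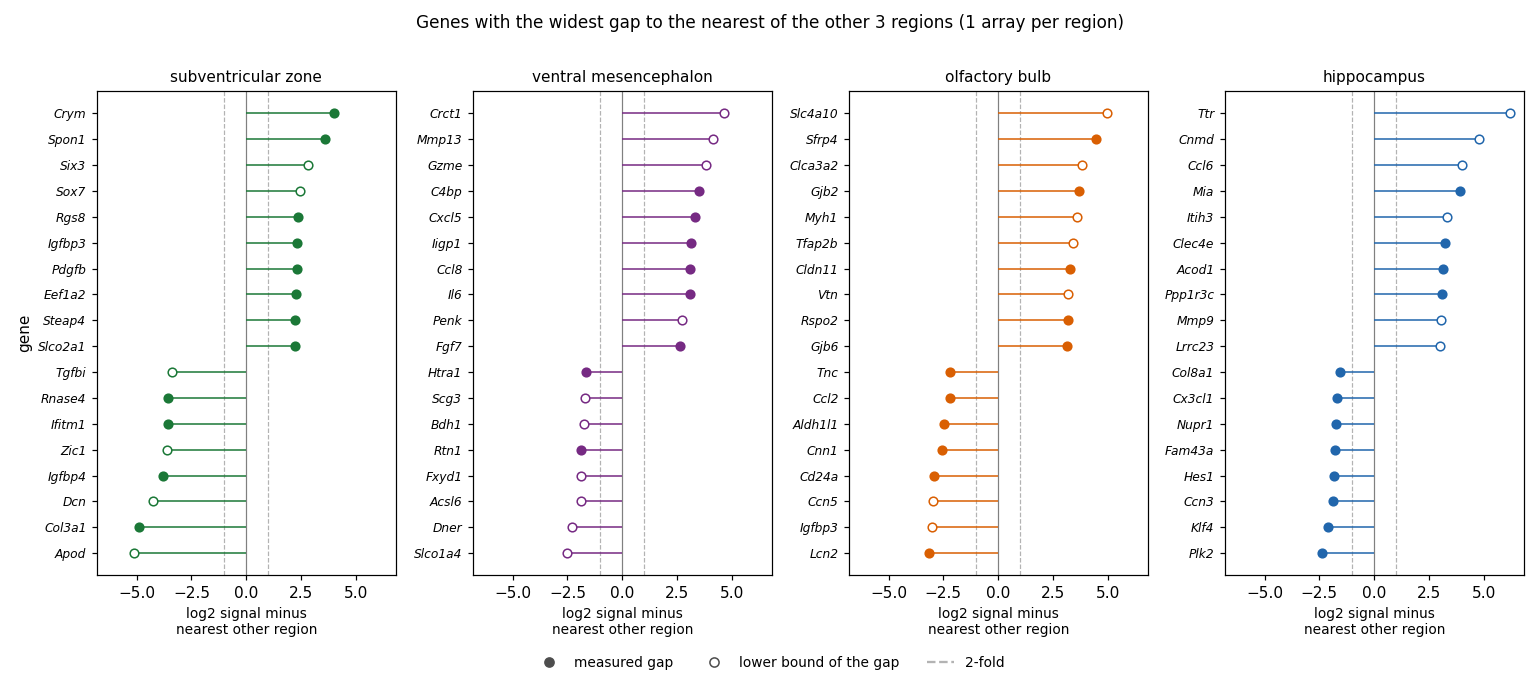
Log2 signal minus that of the nearest other region for the 10 genes higher and the 8 genes lower by the widest gap in each culture, 1 array per region; open circles are lower bounds, where a value was at the floor, and dashed lines mark 2-fold. The widest gaps are those of Ttr in the hippocampus (at least 73.4-fold higher) and Apod in the subventricular zone (at least 35.0-fold lower).

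The ventral mesencephalon culture had the highest interferon and cytokine list medians of the 4, together with midbrain transcription factors and low astrocyte genes. Single cytokines were divided, with 7 of 29 called higher there and 6 in the hippocampus. There, 125 genes were at least 2-fold higher than in each other region and 45 lower. Crct1 was at least 25.0-fold higher (3053), the collagenase Mmp13 at least 17.8-fold (2174) and the granzyme Gzme at least 14.1-fold (1721). The complement regulator C4bp followed at 11.3-fold, the chemokine Cxcl5 at 9.9-fold, the interferon-inducible GTPase Iigp1 at 8.7-fold, the chemokine Ccl8 at 8.6-fold, interleukin-6 (Il6, 5495) at 8.5-fold, the enkephalin precursor Penk at 6.6-fold or more and the growth factor Fgf7 at 6.3-fold. On the low side were the organic anion transporter Slco1a4 (at least 5.8-fold), Dner (at least 4.9-fold), the acyl-CoA synthetase Acsl6 and the sodium pump regulator Fxyd1 (each at least 3.7-fold), Rtn1 (3.6-fold), the ketone body enzyme Bdh1 (at least 3.3-fold), the granin Scg3 (at least 3.2-fold) and the protease Htra1 (3.1-fold).

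Of 31 interferon response and antigen presentation genes, 29 lay above the mean of the other regions in the ventral mesencephalon and 13 were at least 2-fold higher than in each (median 1.81, percentile 100). Beside Iigp1, the antiviral GTPase genes Mx2 (at least 3.7-fold) and Mx1 (at least 2.7-fold) and the oligoadenylate synthetase Oas2 (at least 3.6-fold) had the widest gaps. Ifit3 (8274) and Ifit1 (8007) were 2.0-fold and 2.4-fold above the subventricular zone. Of 29 cytokines and chemokines 7 were higher and none lower (median 0.57, percentile 100): Cxcl5, Ccl8 and Il6, the prostaglandin synthase Ptgs2 (5.9-fold, 6113), Il33 (5.3-fold), Ccl5 (3.9-fold, 4803) and Ccl7 (2.6-fold). The microglia and macrophage list was at its second lowest median in this culture (-1.91), and none of its 29 genes was higher there. The reactive astrocyte list had a median of 0.58 (30 genes, percentile 100), with Iigp1, Timp1 (3.2-fold, 8024) and Gbp2 (2.3-fold) higher and Gfap 3.1-fold lower. The cytokine median was 0.86 without the subventricular zone array.

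Midbrain transcription factors were high and telencephalic ones low in the ventral mesencephalon. The midbrain and floor plate list had a median of 0.27 (17 genes, percentile 99.94), with the winged-helix factor Foxa1 (483, at least 4.0-fold higher) and the engrailed gene En2 (442, at least 3.6-fold) at or below 16.5 on every other array; over all members it was 0.00 and no longer apart. The telencephalic list had a median of -0.71 (10 genes, percentile 0.0), and was no longer apart at -0.20 without the hippocampus array, -0.34 (percentile 3.84) with genes of several lists left out and 0.00 over all members. None of its members was called, and the widest shifts were those of Lhx2 (22.2), Hopx (283), Zbtb20 (414) and Six3 (38.0). All 31 Hox genes named on the array lay below the floor in all 4 cultures.

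Matrix and fibroblast genes were high in the ventral mesencephalon. The extracellular matrix list had a median of 0.81 (50 genes, percentile 100), with 8 genes higher and 2 lower. Mmp13 and Timp1 were joined by the proteoglycan Lum (2.8-fold), Thbs2 (2.8-fold, 4982) and Fbln2 (2.8-fold), and the brain proteoglycan Ncan (2.1-fold) and Nid2 (2.3-fold) were lower. The fibroblast and meningeal list was at 0.86 in the same culture, with Lum and Thbs2 its 2 called members. Among 28 BMP and TGF-beta genes (median 0.29, percentile 99.97) the activin subunit Inhba was 4.0-fold and Ltbp2 3.3-fold higher. Of 28 growth factors, Fgf7, the dopamine neuron survival factor Gdnf (at least 3.2-fold, 396) and Vegfc (2.1-fold) were higher, and the list did not stand apart (median 0.05, percentile 93.46). Of 28 Wnt genes the secreted inhibitor Wif1 (at least 5.8-fold) was higher. Without the subventricular zone array the matrix median was 0.52 and the fibroblast median 0.32, the fibroblast median was 1.72 without the olfactory bulb array, and the BMP and TGF-beta median was 0.44 without the hippocampus array.

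Astrocyte and other glial genes were low in the ventral mesencephalon. Of the 33 astrocyte genes 5 were lower, Gfap 3.1-fold, the aldolase Aldoc 2.8-fold, Acsbg1 at least 2.8-fold, clusterin (Clu) 2.4-fold and Ttyh1 at least 2.0-fold, and 1, the deiodinase Dio2, was 4.2-fold higher. The glutamate, GABA and ion handling list had a median of -0.55 (20 genes, percentile 0.0), with no gene called and Kcnj10 (376), Atp1b2 (551), Slc1a3 (641) and Kcnk1 (26.6) shifted most. The oligodendrocyte lineage list was at -0.61 (11 genes), the ensheathing and Schwann cell list at -0.44, the ependymal list at -0.78 and the choroid plexus list at -0.65, with percentiles of 0.0, 0.07, 0.0 and 0.0. Egr2 (3.5-fold) and Fbln2 of the ensheathing list were higher; in the other lists no gene was called, and Cldn11 (124), Olig1 (621), Rsph1 (75.6), Rarres2 (55.3), Aqp1 (142) and Ttr (1.0) were among those shifted most. Of 44 cell cycle genes, none was called (median 0.14, percentile 99.9); the median turned to -0.13 without the olfactory bulb array and to -0.02 with the floor at the 70th percentile, and was 0.09 and no longer apart as the mean over members. Without the olfactory bulb array the ensheathing list was at 0.00, and without the hippocampus array the ependymal and choroid lists were at -0.02 and 0.00; none of these stood apart. With the floor at the 30th percentile the oligodendrocyte list was at -0.22 (percentile 18.61) and the choroid list at -0.45 (percentile 6.0), both no longer apart, as was the ensheathing list with the floor at the 70th percentile (-0.10) or the mean over members (-0.18). Without the subventricular zone array 285 genes were higher and 211 lower, and without the olfactory bulb array 248 and 239. With the floor at the 70th percentile Slco1a4, Dner, Acsl6, Fxyd1, Bdh1 and Scg3 were less than 2-fold lower (log2 gaps 0.97, 0.73, 0.34, 0.32, 0.17 and 0.11), and Bdh1 also as the mean of its probe sets (0.87). Some medians moved without losing their place: choroid plexus to -1.11 without the subventricular zone or the olfactory bulb array, ependyma to -1.43 without the olfactory bulb array, ensheathing cells to -0.68 without the subventricular zone array, and oligodendrocytes to -0.38 and cell cycle to 0.27 without the hippocampus array.

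The olfactory bulb culture differed most from the subventricular zone and carried genes of meninges, ensheathing cells and microglia, with low cell cycle, progenitor and inflammatory genes. There, 149 genes were at least 2-fold higher than in each other region and 124 lower. The sodium bicarbonate transporter Slc4a10 was at least 30.9-fold higher (3774), the secreted Wnt inhibitor Sfrp4 21.8-fold (6384) and the connexin Gjb2 12.8-fold (5291). On the low side lipocalin-2 (Lcn2, 694 against 6298 to 17145) was 9.1-fold, Igfbp3 at least 8.0-fold and Ccn5 at least 7.9-fold lower. Other genes on the high side were Clca3a2 (at least 13.9-fold), the skeletal myosin Myh1 (at least 11.9-fold), the neural crest factor Tfap2b (at least 10.6-fold), the tight junction protein Cldn11 (9.5-fold), vitronectin (Vtn, at least 9.1-fold), the Wnt agonist Rspo2 (9.0-fold) and the connexin Gjb6 (8.9-fold). Cd24a was 7.6-fold lower, calponin (Cnn1) 5.9-fold, Aldh1l1 5.5-fold, and the chemokine Ccl2 and tenascin-C (Tnc) each 4.7-fold.

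Of the 26 fibroblast and meningeal markers 6 were higher in the olfactory bulb and none lower (median 1.43): the forkhead gene Foxc2 was 5.5-fold higher (4041), periostin (Postn) 4.1-fold, Ogn 3.6-fold (6417) and Col6a2 2.9-fold. The extracellular matrix list had a median of 0.41 (percentile 100), with Postn, Nid1 (3.1-fold) and Omd (2.7-fold) higher and Tnc lower; it was 0.16 and no longer apart without the subventricular zone array. Of 18 olfactory ensheathing and Schwann cell markers 7 were higher (median 0.51, percentile 100); with the floor at the 70th percentile the median was 0.13 (percentile 81.89) and no longer apart. These were Vtn, the neurotrophin receptor Ngfr (4.2-fold, 662), the adhesion molecule L1cam (at least 3.8-fold), Ccn3 (3.4-fold), Sox10 (at least 2.9-fold), Aspa (at least 2.5-fold) and Gfra3 (at least 2.3-fold). Fabp7, which stands in the astrocyte and progenitor lists too, was 3.6-fold lower, and 8 of the 18 stand in another list. Microglial markers were at 1.52 in this culture, with none called; C1qa read 3325 there and 3527 in the hippocampus, and Tyrobp 2940 and 3061. Without the subventricular zone array the fibroblast median was 0.90; without the hippocampus array the matrix median was 0.26 and the microglial one 2.60.

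Of 28 Wnt genes 5 were higher in the olfactory bulb, Sfrp4, Rspo2, Wnt6 (at least 5.2-fold), Fzd2 (2.3-fold) and Fzd7 (2.1-fold), while the median of the list, -0.06, did not stand apart. The guidance genes Unc5c (7.4-fold), Plxna2 (3.8-fold) and Sema3a (2.4-fold) were higher with L1cam, and that list was at 0.08 (percentile 95.91). Gjb2, Gjb6, the bicarbonate transporter Slc4a4 (2.7-fold) and the cystine transporter Slc7a11 (2.6-fold) were higher in the glutamate, GABA and ion handling list, whose median was 0.37 (percentile 99.88); it lost its place apart under 6 of the 10 alternatives chosen before, as with genes of several lists left out (0.09). The astrocyte list held Gjb6 and Slc4a4 on the high side and Aldh1l1, Fabp7 and tissue factor (F3, 3.5-fold) on the low side. The 7 hedgehog genes had a median of 0.47 (percentile 98.72), with the receptor Ptch1 2.5-fold lower; it was 0.39 and no longer apart without the ventral mesencephalon array, turned to -0.11 with the floor at the 30th percentile, and lost its place under 5 of the 10 alternatives in all. Of 28 BMP and TGF-beta genes (median 0.00, percentile 53.38) Gdf10 was at least 3.2-fold higher, and Tgfb3 (3.5-fold), Ltbp2 (3.3-fold) and Inhbb (at least 2.8-fold) were lower. Of 11 oligodendrocyte lineage markers (median -0.25, percentile 8.6) Cldn11 and Sox10 were higher and Olig1 3.6-fold lower. The reelin gene Reln was at least 4.4-fold higher (542).

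Progenitor, cell cycle and inflammatory genes were low in the olfactory bulb. The neural stem and progenitor list had a median of -0.86 (percentile 0.0), with 6 members lower and 2 higher. Cd24a, Tnc, Fabp7 and the stem cell factor Sox2 (2.8-fold, 348) had the widest gaps on the low side, followed by prominin (Prom1, at least 2.7-fold) and Vcam1 (2.2-fold). The antiproliferative gene Btg2 (3.9-fold) and the growth factor receptor Egfr (2.4-fold) were higher. The cell cycle list of 44 genes, none shared with another list, had a median of -0.80 (percentile 0.0); 3 members lay above the mean of the other regions, and the spindle factor Tpx2 (2.5-fold) and the kinase Cdk1 (2.4-fold) were lower. Of 30 reactive astrocyte genes 7 were lower and none higher (median -0.81, percentile 0.0), with Lcn2, the serpin Serpina3n (3.7-fold), the cytokine Clcf1 (at least 3.4-fold) and Cxcl10 (at least 3.2-fold) furthest. Interferon genes (median -0.95, 4 lower) and cytokines (-0.95, 4 lower) were both at percentile 0.0, with Ccl2, Ccl7 (4.3-fold), Rsad2 (3.6-fold) and Bst2 (3.3-fold) among those lower. Without the hippocampus array the progenitor median was -0.49, the interferon median -1.46 and the cytokine median -0.63; the cytokine median was -0.55 without the ventral mesencephalon array.

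Of the growth factors, Igf2 was 3.0-fold higher (10268) in the olfactory bulb and Igfbp3 and Hbegf (2.9-fold) lower, with a list median of -0.52 (percentile 0.0) that was -0.15 and no longer apart without the ventral mesencephalon array. Neuronal markers were at -0.58 (percentile 0.0; Stmn2 2.4-fold lower) and ependymal markers at -1.0 (percentile 0.0; Foxj1 at least 2.5-fold and Ezr 2.2-fold lower). The neuronal median was -0.30 without the subventricular zone array and the ependymal one -0.04 without the hippocampus array, both no longer apart. Over all members the growth factor and neuronal medians were 0.00 and not apart. Without the ventral mesencephalon array 303 genes were higher and 306 lower in the olfactory bulb, and without the hippocampus array 316 and 299. With only probe sets of a plain identifier, Myh1 and Aldh1l1 were both at the floor on all arrays and had no gap (log2 0.00). Their chosen probe sets end in _a_at and were left out by that setting. The ependymal median was -1.60 without the ventral mesencephalon array.

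The hippocampus culture carried genes of choroid plexus, ependyma and microglia, together with the highest astrocyte and cell cycle medians. There, 199 genes were at least 2-fold higher than in each other region and 39 lower. Transthyretin (Ttr), the main secreted protein of the choroid plexus, was at least 73.4-fold higher (8960 against 88.1 or less), Cnmd at least 27.2-fold (3323) and the chemokine Ccl6 at least 16.2-fold (1978). Mia followed at 14.9-fold, the inter-alpha-trypsin inhibitor chain Itih3 at 10.0-fold or more, the lectin receptor Clec4e at 9.4-fold, the itaconate-producing enzyme Acod1 at 8.9-fold, the glycogen phosphatase subunit Ppp1r3c at 8.6-fold, the gelatinase Mmp9 at 8.4-fold or more and Lrrc23 at 7.9-fold or more. On the low side were the kinase Plk2 (5.2-fold), the transcription factor Klf4 (4.3-fold), Ccn3 (3.6-fold), the Notch target Hes1 (3.6-fold), Fam43a (3.4-fold), the stress protein Nupr1 (3.3-fold), the chemokine Cx3cl1 (3.2-fold) and the collagen Col8a1 (3.0-fold).

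Of 10 ependymal and motile cilia markers 8 were higher in the hippocampus (median 1.80, percentile 100): Mia, Rsph1 (5.0-fold), Tekt1 (at least 3.4-fold) and Spag6l (at least 2.9-fold) had the widest gaps, and Foxj1, the master regulator of motile cilia, was 2.1-fold higher (1910). Of 8 choroid plexus markers 3 were higher (median 2.01, percentile 100), Ttr, Calml4 (7.2-fold, 1301) and the folate receptor Folr1 (at least 4.5-fold). Of 29 microglial markers 28 lay above the mean of the other regions and 7 were higher than in each (median 2.58): Ccl3 (at least 6.3-fold), Cd52 (3.3-fold), Ly86 (2.9-fold) and Cd53 (2.8-fold) led, followed by Cx3cr1 (2.6-fold), Cd14 (2.5-fold) and Ccl4 (2.4-fold). Chemokines of this set stood beside them, with Ccl6, Ccl12 (6.4-fold), Ccl3 and Ccl9 (2.7-fold) among 6 cytokines that were higher, while the median of the 29 cytokines was -0.38 (percentile 0.0) and 0.00, no longer apart, without the ventral mesencephalon array. Oligodendrocyte lineage markers were at 0.38 (11 genes, percentile 98.03), with Pdgfra 2.8-fold and Cnp 2.0-fold higher, and no longer stood apart without the subventricular zone array (percentile 97.25) or over all members (0.00). The cytokine median was -0.23 without the subventricular zone array.

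Of the 33 astrocyte genes 4 were higher in the hippocampus and none lower: Gpr37l1 4.5-fold, Gfap 2.6-fold, Ndrg2 2.5-fold and the sodium pump subunit Atp1b2 2.5-fold. The telencephalic transcription factors were at 0.90 (10 genes, percentile 100), with Pax6 3.4-fold and the cortical factor Fezf2 at least 2.0-fold higher. The ventral telencephalic list had a median of -0.21 (9 genes, percentile 2.22), with none called and Meis2 (639.9), Foxp1 (503), Six3 (42.9) and Zic1 (1503) shifted most. It no longer stood apart without the subventricular zone (-0.18), the ventral mesencephalon (-0.18) or the olfactory bulb array (-0.01), nor under 8 of the 10 alternatives chosen before. The neural stem and progenitor list was at 0.46 (percentile 100), with Pax6, Igfbpl1 (2.5-fold) and Ptprz1 (2.3-fold) higher and Hes1 lower, but turned to -0.29 (percentile 0.23) without the olfactory bulb array. Of 30 reactive astrocyte genes the proteoglycan Srgn (4.0-fold), Gfap and Cd14 were higher, with a median of 0.00 (percentile 74.78). Of 44 cell cycle genes 37 lay above the mean of the other regions (median 0.58, percentile 100), with Cdc20 (2.2-fold) and Mki67 (2.1-fold) higher. Without the subventricular zone array the astrocyte median was 1.08 and the progenitor median 0.83, and without the olfactory bulb array the cell cycle median was 0.28. Over all members the telencephalic and progenitor medians were 0.00 and no longer apart.

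Interferon genes had a median of -1.03 in the hippocampus (percentile 0.0), and one of -0.23 for the olfactory bulb minus the hippocampus, with no gene above the mean of the other regions and the GTPase Ifi47 2.7-fold lower. Extracellular matrix genes were at -0.55 (percentile 0.0), with Mmp9 and Col11a1 (2.3-fold) higher and Col8a1 and Loxl1 (2.1-fold) lower, and the fibroblast marker Twist1 was at least 2.1-fold lower. The axon guidance list was at -0.32 (percentile 0.0), with Cntn1 (at least 2.4-fold) and Cdh4 (at least 2.2-fold) higher and the ephrin Efnb2 2.9-fold lower. BMP and TGF-beta genes were at -0.23 (percentile 0.22; Bmp6 2.8-fold higher, Smad7 2.1-fold lower), Wnt genes at -0.13 (percentile 1.36) with Rspo2 (111), Fzd7 (446), Sfrp4 (292) and Wnt7a (343) shifted most, and ensheathing markers at -0.32 (percentile 0.07; Mia and Npy, 2.2-fold, higher, Ccn3 and Egr2, at least 2.4-fold, lower). BMP and TGF-beta genes were at -0.16 without the subventricular zone array, Wnt genes at -0.01 without the ventral mesencephalon and -0.07 without the olfactory bulb array, and ensheathing markers at 0.00 without the olfactory bulb array; none then stood apart. Of the 10 alternatives chosen before, 2, 3 and 4 ended the place apart of these lists in turn. Without the subventricular zone array 425 genes were higher and 175 lower in the hippocampus, and without the olfactory bulb array 360.0 and 197. Klf4, Hes1 and Cx3cl1 were less than 2-fold lower with the floor at the 70th percentile (log2 gaps 0.97, 0.37 and 0.59), and Cx3cl1 and Col8a1 with the mean of all probe sets (0.64 and 0.79). Without the ventral mesencephalon array the interferon median was -0.59 and the matrix median -0.23; without the olfactory bulb array the matrix median was -0.26 and the BMP and TGF-beta median -0.35, and the axon guidance median was -0.20 without either.

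**Figure D3:**
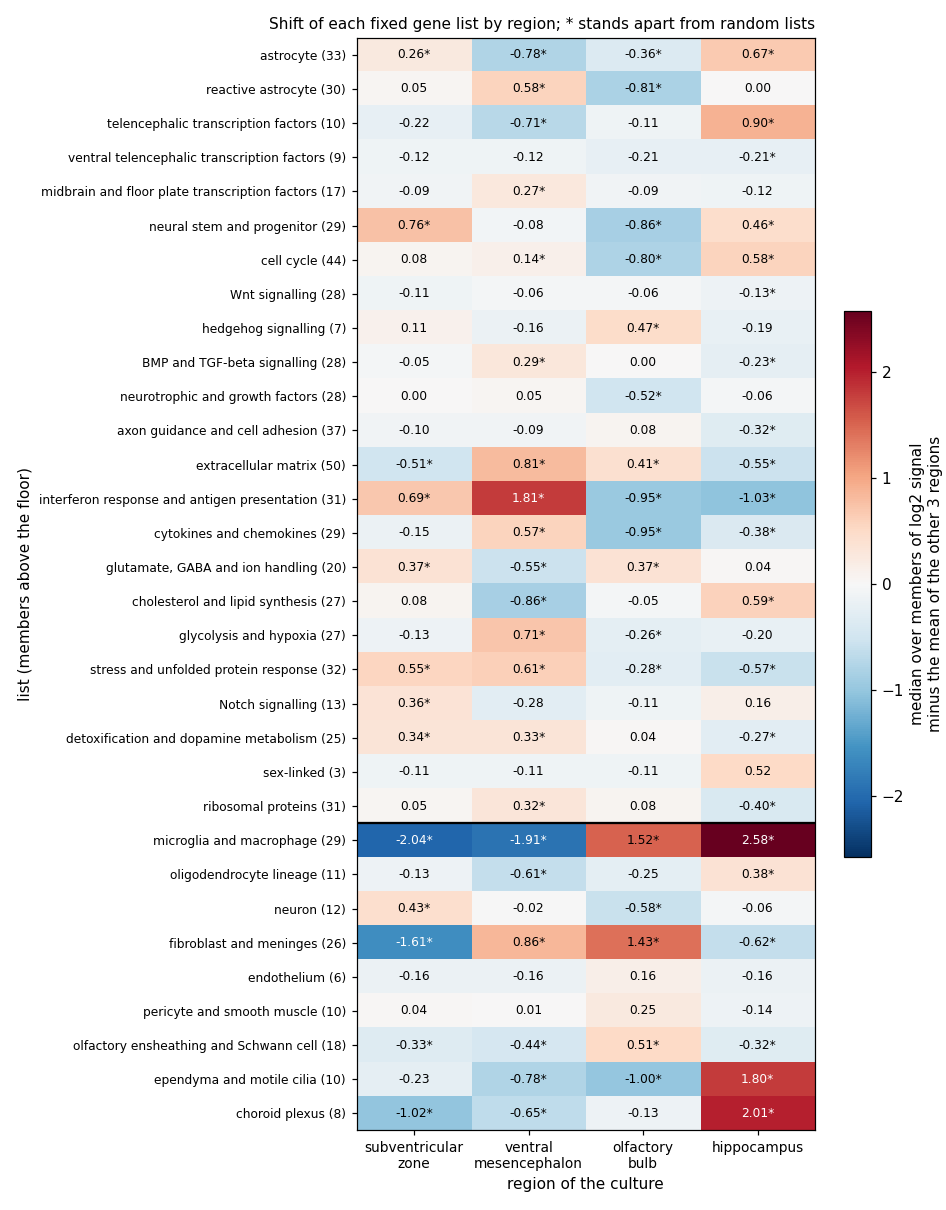
Median over list members of log2 signal minus the mean of the other 3 regions, for 23 gene lists (above the line) and 9 cell type marker lists (below), 1 column per region and 1 array each; the number of members above the floor is in brackets and an asterisk marks a median that stands apart from random lists. The widest medians are those of the microglial list, at 2.58 in the hippocampus and -2.04 in the subventricular zone.

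Between pairs of regions, the subventricular zone and the olfactory bulb lay furthest apart and the subventricular zone and the ventral mesencephalon closest. Of the 7987 genes above the floor, 1389 (17.4%) differed 2-fold or more between the first pair, 719 higher in the subventricular zone and 670.0 in the olfactory bulb, with a Pearson correlation of 0.812 and a Spearman correlation of 0.785 across genes, which are not independent replicates. Between the subventricular zone and the ventral mesencephalon 832 genes (10.4%) differed, 435 and 397, with correlations of 0.896 and 0.877. The axon guidance cue Ntn1 (4730 against 69.6, at least 38.7-fold) and Igfbp3 (at least 50.4-fold) led the genes higher in the subventricular zone than in the olfactory bulb with Crym (at least 33.5-fold), and Igf2 (at least 84.1-fold), Apod (at least 65.0-fold) and Lyz2 (62.8-fold) those higher in the olfactory bulb. Against the ventral mesencephalon, the subventricular zone was higher in the synaptic organiser C1ql3 (19.4-fold), Spon1 (at least 19.2-fold) and the forebrain homeobox gene Lhx2 (at least 16.6-fold), and lower in Col3a1 (53.3-fold), Dcn (at least 51.8-fold) and Apod (at least 36.9-fold).

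The remaining pairs fell between these. The ventral mesencephalon and hippocampus differed in 1294 genes (16.2%), 541 higher in the first and 753 in the second; Il6 (at least 45.0-fold), Ccl5 (at least 39.3-fold) and Cxcl11 (30-fold) led the first group, and Lyz2 (at least 73.8-fold), Ttr (at least 73.4-fold) and the related lysozyme Lyz1 (67.6-fold) the second. The olfactory bulb and hippocampus differed in 1112 genes (13.9%), 418 and 694. Slc4a10 (at least 30.9-fold), thrombomodulin (Thbd, 28.1-fold) and Rspo2 (at least 27.9-fold) were higher in the bulb, and Ttr, Cnmd (at least 27.2-fold) and Acod1 (17.0-fold) in the hippocampus. The ventral mesencephalon and olfactory bulb differed in 958 genes (12%), 516 and 442, with Il6 (at least 45.0-fold), Cxcl10 (at least 41.7-fold) and Ccl5 (at least 39.3-fold) against Lyz2 (at least 92.1-fold), Lyz1 (84.1-fold) and Csf1r (at least 33.4-fold). The subventricular zone and hippocampus differed in 917 genes (11.5%), 395 and 522, with Ntn1 (35.7-fold), Crym (at least 33.5-fold) and Cxcl11 (17.2-fold) against Ttr (at least 73.4-fold), Lyz2 (50.4-fold) and Csf1r (at least 41.8-fold). Pearson and Spearman correlations of these 4 pairs ran from 0.829 and 0.802 for the ventral mesencephalon and hippocampus to 0.873 and 0.850 for the subventricular zone and hippocampus. Microglial markers moved with the pairs that crossed from the subventricular zone or ventral mesencephalon to the olfactory bulb or hippocampus, with 24 to 27 of 29 genes 2-fold or more higher in the latter, against 1 gene each way between the first 2 regions.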

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

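Leaving out each other array and leaving out the cell type marker genes were chosen after seeing the data; the others were chosen before. No paired analysis was possible because all 4 samples are replicate 1 of their region, 1 per region, so the groups share fewer than 2 numbers and the results come from no test. Of 72 region counts under the other alternatives 36 stayed within 1.5-fold, as did 30 of 54 pair counts. Of 1280 list medians 1137 kept their side of the limits, 71 no longer stood apart, 70 newly did and 2 turned round. A change of sign was counted only for medians that stood apart at first, so sign changes of the others are not included. Of 493 named gene results 476 stayed past 2-fold. Named genes were those with the widest gaps, so this count does not describe all called genes. With the floor at the 70th percentile, 33.3% to 58.4% of the genes called in each region and direction were still called. The share was 51.3% to 74.4% with an offset in place of the floor and 86.9% to 98.4% after quantile normalization. With the mean of all probe sets the lowest share was 53.3%.

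With the floor at the 30th percentile (25.2), genes higher and lower numbered 168 and 197 in the subventricular zone, 205 and 109 in the ventral mesencephalon and 371 and 68 in the hippocampus, and 282 were lower in the olfactory bulb. Pairs differed in 1404 (subventricular zone and ventral mesencephalon), 2264 (subventricular zone and olfactory bulb), 1601 (subventricular zone and hippocampus), 1649 (ventral mesencephalon and olfactory bulb), 2090.0 (ventral mesencephalon and hippocampus) and 1835 genes (olfactory bulb and hippocampus). With the floor at the 70th percentile (360.4), the region counts were 56 and 32, 73 and 15, 86 and 55, and 94 and 20 (subventricular zone, ventral mesencephalon, olfactory bulb, hippocampus), and the pair counts, in the order above, 436, 737, 460.0, 491, 697 and 573. A floor sets how many genes can reach a fold, so these counts move by construction; signal over background limits how far genes near the floor can be compared.

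By construction too, a threshold of 1.5-fold gave 287 and 224, 288 and 169, 377 and 362, and 502 and 135 genes in the same order of regions, and pair counts of 1804, 2767, 2110.0, 2226, 2611 and 2388; a threshold of 3-fold gave 27 and 35, 53 and 13, 61 and 33, and 59 and 7, and pair counts of 353, 646, 382, 418, 583 and 419. An offset in place of the floor gave 67 genes higher in the subventricular zone and 132 higher and 20 lower in the hippocampus, and the mean of all probe sets 27 lower in the ventral mesencephalon and 21 in the hippocampus; the cause was not tested. The hedgehog median in the olfactory bulb turned to -0.11 with the lower floor and the cell cycle median in the ventral mesencephalon to -0.02 with the higher one; the cause was not tested.

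Of the 72 list medians that stood apart, 43 did so under all 10 alternatives chosen before, and 29 lost this place under 1 or more. The losses were 8 for ventral telencephalic factors in the hippocampus, 7 for Notch in the subventricular zone, 6 for glutamate, GABA and ion handling in the olfactory bulb and 3 in the subventricular zone, and 5 for hedgehog in the olfactory bulb. There were 4 for detoxification in the ventral mesencephalon and in the hippocampus and for ensheathing cells in the subventricular zone and in the hippocampus, and 3 for Wnt in the hippocampus. There were 2 each for BMP and TGF-beta in the hippocampus, astrocyte genes and neurons in the subventricular zone, and cell cycle, ensheathing cells and telencephalic factors in the ventral mesencephalon. There was 1 each in the subventricular zone for detoxification; in the ventral mesencephalon for choroid plexus, midbrain factors, oligodendrocytes and ribosomal proteins; in the olfactory bulb for astrocyte genes, neurons, growth factors and ensheathing cells; and in the hippocampus for progenitors, oligodendrocytes, ribosomal proteins and telencephalic factors.

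Without 1 of the other arrays, a region is compared with 2 regions and more genes pass by construction. Genes higher and lower ranged from 114 to 304 and 94 to 249 in the subventricular zone, 139 to 285 and 55 to 239 in the ventral mesencephalon, 163 to 316 and 159 to 306 in the olfactory bulb, and 221 to 425 and 49 to 197 in the hippocampus. List medians ranged from -0.01 to 0.45 for astrocyte genes in the subventricular zone, -0.29 to 0.83 for progenitor genes in the hippocampus and -0.13 to 0.27 for cell cycle genes in the ventral mesencephalon. Of 384 list medians 318 kept their side of the limits, 33 no longer stood apart, 30 newly did and 3 turned round. Sign changes were again counted only for medians that stood apart at first. A named gene's gap to the nearest region can only stay or widen here, so these settings say nothing about named genes. With cell type marker genes left out, 94 genes were higher and 72 lower in the subventricular zone, 120.0 and 44 in the ventral mesencephalon, 133 and 118 in the olfactory bulb and 178 and 35 in the hippocampus.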

Other observations

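Of the tests below, those of activation alone and of 1 probe set per gene in called members were written before their results were seen, and the others were chosen after.

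Lipid synthesis genes split the ventral mesencephalon from the hippocampus. Of 27 cholesterol and lipid synthesis genes, 0 lay above the mean of the other regions in the ventral mesencephalon (median -0.86, percentile 0.0) and 25 did in the hippocampus (0.59, percentile 100). The desaturase Scd1 was 2.9-fold lower in the ventral mesencephalon; Fads2 read 509 there and 2291 in the hippocampus, and Sqle 432 and 1512. Of 27 glycolysis and hypoxia genes 22 lay above that mean in the ventral mesencephalon (median 0.71, percentile 100), with Bnip3 (2.8-fold) and Adm (2.7-fold) higher and Aldoc (2.8-fold) and Ndrg1 (2.7-fold) lower. In the olfactory bulb the median was -0.26 (percentile 0.39), with Pfkfb3 3.7-fold and the glucose transporter Slc2a1 3.2-fold lower, and -0.15, no longer apart, without the ventral mesencephalon array; without the hippocampus array it was -0.49.

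Stress and unfolded protein response genes (32) were at 0.55 in the subventricular zone, 0.61 in the ventral mesencephalon, -0.28 in the olfactory bulb and -0.57 in the hippocampus (percentiles 100, 100, 0.03 and 0.0). Ddit3 read 1920, 1666, 318 and 349 in these regions and Atf3 1173, 718, 253 and 282; Hspa1b was 2.1-fold lower in the subventricular zone and Hmox1 4.4-fold lower in the olfactory bulb, whose median was -0.12 without the subventricular zone and -0.15 without the ventral mesencephalon array, no longer apart. The 25 detoxification and dopamine metabolism genes were at 0.34, 0.33, 0.04 and -0.27 (percentiles 99.93, 99.96, 51.56 and 0.8). Aldh1a1 was 2.2-fold higher in the subventricular zone and 2.5-fold lower in the ventral mesencephalon, Mt3 2.9-fold lower in the latter, and Gch1 at least 3.0-fold lower in the olfactory bulb. The ventral mesencephalon median was 0.10 without the subventricular zone and 0.06 without the olfactory bulb array, and the hippocampus median -0.04 without the subventricular zone and -0.23 without the ventral mesencephalon array, none of them apart. Each of these 2 medians also lost its place apart under 4 of the 10 alternatives chosen before; in the ventral mesencephalon these were the floor at the 70th percentile (0.01), the mean over members (0.12), all members (0.02) and no shared members (0.03). The subventricular zone median was 0.24 (percentile 96.2) and no longer apart as the mean over members. Without the hippocampus array the stress medians were 0.30 in the subventricular zone, 0.39 in the ventral mesencephalon and -0.63 in the olfactory bulb, and the detoxification median 0.14 in the ventral mesencephalon.

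Ribosomal protein genes (31) were at 0.05, 0.32, 0.08 and -0.40 (percentiles 45.82, 99.99, 62.77 and 0.02). Rps26 (4754), Rplp0 (7750), Rps6 (494) and Rpl27 (5138) were shifted most in the hippocampus, whose median was -0.09 and no longer apart after quantile normalization. That of the ventral mesencephalon was 0.24 (percentile 92.27) and no longer apart with only probe sets of a plain identifier. The signals of all 18 hybridisation control probe sets fell from the subventricular zone over the ventral mesencephalon and olfactory bulb to the hippocampus, by a median of 1.69-fold from first to last (1.55 to 1.86).

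Xist and the Y-linked genes were not level across cultures described as pooled from pups. Scaling between arrays would have to close the gap in Xist, but its smallest log2 difference between olfactory bulb and subventricular zone was 3.18 over 3 scalings. These scalings differ little, with median deviations of genes above the floor on all arrays from -0.04 to 0.05. The result was thus nearly fixed in advance and shows only that the choice among them does not matter. An error of a single probe set would leave the others level, but 3 of 3 Xist probe sets were above the subventricular zone and ventral mesencephalon in both the olfactory bulb and the hippocampus. Of these, 3 were above the floor in the olfactory bulb and 2 in the hippocampus, where the third read 36.3. Pups of different sex behind the 4 cultures may be the source: 4 of 4 genes escaping X inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) had their highest signal in the olfactory bulb. The lead of Ddx3x was small (4330 against 4153 in the ventral mesencephalon), and Kdm5c read 140.7, near the floor. In the hippocampus, Kdm6a (177) and Eif2s3x (1763) came next after the bulb by the chosen probe sets, but Kdm5c (106) was below the floor. Ddx3x (3225) was lowest there, although Xist was present. Other probe sets were divided. By another one, Kdm6a was lower in the hippocampus (155.8) than in the ventral mesencephalon (184.6). For Eif2s3x, another was lowest in the hippocampus (1518.5), and a further one (262.8) came next after the bulb. The sex of the pups is not given in the sources used here, so this remains a hypothesis. If it holds, the cultures also differ in the pups behind them. Differences between regions could then not be told apart from differences between pups or sexes.

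Microglial markers were higher in the olfactory bulb and hippocampus than in the other 2 cultures. Scaling between arrays left a median log2 difference of at least 2.51 under the scalings used for Xist, which differ little. Inflammatory activation alone was predicted to leave lineage markers level, but 12 of these had a median difference of 3.49. These 12 belong to the same list, so their difference partly restates the pattern and does not exclude activation. More microglia or macrophages in those 2 cultures may account for it, but this stays open: that 82.8% (24 of 29) of the markers were 2-fold or more higher on both arrays than on both others restates the pattern and decides nothing. Lyz2 read 11249 and 9016. The cultures had been shaken at 200 rpm, a step that removes loosely attached cells, and 4 of the 29 markers stand in other lists. Region and culture are the same thing in this design, so a regional difference was not tested.

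Interferon response genes were higher in the ventral mesencephalon. Scaling between arrays left a median of at least 1.80 under the scalings used for Xist, which differ little. More microglia or macrophages in that culture would bring their markers, whose median was -1.91. No list of lymphocyte markers was examined, so other leukocytes stay open. An error of the chosen probe sets would vanish in others, but the 8 of 31 members with a second probe set above the floor had a median of 1.15 by it (lower quartile 0.78), against 1.32 by the chosen one, and 8 of 8 lay above the mean of the other regions. The other members have no such second probe set, and the 2-fold calls of single members stay open too, with 3 of 4 (75.0%) called by the second probe set as well. A difference in the state of that culture, which may include its astrocytes, remains open and untested.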
